A study of Mus musculus with 4 samples.

How the data were processed

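Ventricular tissue of mice at 6 months of age was the source of the RNA, with 2 samples from non-transgenic mice and 2 from mice with moderate heart-specific overexpression of SRF. Total RNA was purified on columns, labelled with biotin and hybridised by the Affymetrix procedure, per the labels' protocols. Groups were taken from the transgenic status in the labels. The labels do not say that the samples came from separate animals, so p values measure the spread between these samples, which may be technical.

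The deposited values are one signal intensity per probe set and array, on a linear scale. The scale was settled from the values, which are all above 0, right-skewed and given to 1 decimal. The mean of each array without the top and bottom 2% of probe sets was 150.1, as scaling of all arrays to one target would give. The signal software and the exact scaling are not given in the sources used here, and no detection calls were used. Array medians were 53.9, 52.3, 49.0 and 50.6. Global scaling sets the arrays to a common mean, so a change shared by most RNA is not visible, and a change in very bright transcripts shifts the values of others slightly. The table held 12488 probe sets, of which 66 were controls and were left out of the tests.

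Probe sets were named through the platform annotation, with symbols checked through gene numbers against RefSeq (10839 gene numbers matched and 0 symbols changed). 10833 probe sets had 1 gene symbol, 396 had several and were left unnamed, and 1193 were not listed. Genome coordinates are not used here. Probe sets marked as binding several transcripts, among them those of the Mup and Serpina1 families, can mix the signals of related genes.

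Values were transformed to log2(value + 9), where 9 is the 20th percentile of all positive values, rounded. Fold changes are on this scale and understate the change of dim genes. The array medians of these values lay within 0.2 of each other, so the arrays were used as deposited, by a rule set before the data were examined. Probe sets in the lowest 40% by mean over all 4 arrays were left out, without regard to group, and 7453 remained.

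Groups were compared with lmFit and eBayes (trend of variance on signal) of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The prior carried 5.05 degrees of freedom, more than the 2 residual degrees of freedom of the design. Errors given beside log2 changes are moderated standard errors, and errors beside signals are standard deviations. Gene lists fixed before the data were examined were tested with camera of limma (preset correlation 0.01, 1 probe set per gene, the brightest over all arrays) where at least 4 members were tested, which held for 29 of 31 lists. Camera was repeated with an estimated correlation, and fry was run beside it. The repeat with an estimated correlation refers each list to the 2 residual degrees of freedom of the design. It therefore has little power here, and a list that does not pass it is not thereby shown to be unmoved. For each list the members were also adjusted over the list alone.

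Named genes were the 12 with the largest change in each direction among those past the threshold with a single symbol and no overlap between groups. From each list, up to 4 members with the smallest p were added, and any member past the threshold. Because all 12 largest falls were hepatocyte genes, the same rule was applied once more outside the hepatocyte list, after the values were seen. The lists of hepatocyte, pancreas, kidney and lung genes and of some further groups were also written after the values were seen, and the hepatocyte list was corrected later, when 2 of its name patterns were found to take in unrelated genes.

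The alternatives planned before the data were examined were other pseudocounts, median centring, quantile normalization, other filters, other variance models, an ordinary test, a looser threshold, a block for replicate number, and leaving out each array in turn. Leaving out the hepatocyte list was added later. Permutation tests over genes used 1e+05 resamples, or all groupings where these were few enough to enumerate. The latter held for the comparison of cytosolic and mitochondrial thiol defence genes (319770 groupings). The test for liver RNA was first run on called members alone, which favours agreement between the non-transgenic arrays, and was replaced by one over all tested members.

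The fit was tested on simulated arrays with the means of these data and the spread of limma's fitted trend and prior. Errors were drawn independently for each gene. The simulations therefore cannot test correlated genes within lists or a departure from limma's variance model. In 10 simulations with 200 of 7453 probe sets changed 2-fold, 38.9% of the changed probe sets were recovered and 4.86% of those called were false. With 1.5-fold changes 0 were recovered, and with no change 0 were called. The simulated spread came from a fit to all probe sets outside the controls, without the filter of the main fit. The 200 changed probe sets were also fewer than the 1802 with an unadjusted p below 0.05 in the data, which makes the adjustment stricter. The simulations therefore do not set the smallest change that could be called in the data. Camera called the list of 30 genes with 20 moved in 10 of 10 simulations at either fold, and called an unmoved list in 1 and 0 of 10.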

Results

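Ventricular RNA from 4 arrays of mouse heart at 6 months of age was compared, 2 from non-transgenic mice and 2 from mice that overexpressed serum response factor (SRF) moderately and only in the heart. SRF is a transcription factor that binds CArG boxes in the promoters of cytoskeletal, muscle and immediate early genes. Each array was an Affymetrix oligonucleotide array with 12488 probe sets, and each sample was represented by 1 array. The median signal was 53.9 and 52.3 on the non-transgenic arrays and 49.0 and 50.6 on the transgenic arrays. Log2 signals correlated at 0.973 between the non-transgenic arrays and at 0.981 between the transgenic arrays, against 0.961 to 0.964 for pairs taken across the groups. These correlations were taken across probe sets, which are not independent replicates. The number of arrays limits the precision of every value below.

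The question was which ventricular transcripts differ in amount when SRF is overexpressed. Srf itself is not analysed here, so the overexpression was not checked on these arrays. The transgenic ventricle had more RNA for the atrial natriuretic peptide Nppa, for the fast skeletal muscle light chain Myl1 and smooth muscle actin Acta2, and for the matrix genes Ccn2 and Postn. Nppa signal was 436 ± 34.6 in non-transgenic and 1951 ± 102 in transgenic ventricle (mean ± SD, n = 2 each), a 4.41-fold rise. Less RNA was present for enzymes of mitochondrial fatty acid oxidation such as Ech1 and for the calcium-binding protein of the sarcoplasmic reticulum Hrc. A large set of liver transcripts led by Mup3, Apoa1 and Alb was lower too. For these, RNA from liver in the non-transgenic samples is a candidate explanation, which could not be told apart from expression by the heart. Hrc signal was 2423 ± 135 against 864 ± 82.8, which was 2.79-fold lower in the transgenic samples.

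Of 7453 probe sets tested with limma, 303 (265 genes) were higher and 288 (242 genes) lower in transgenic ventricle after Benjamini-Hochberg adjustment, and 1802 had an unadjusted p below 0.05. A change of at least 2-fold was seen in 96 of the higher and 78 of the lower probe sets. Hepatocyte transcripts made up 41 of the lower probe sets and 0 of the higher ones. Without the hepatocyte list, an alternative chosen after seeing the data, the counts were 300 higher and 245 lower. The arrays of the 2 groups did not overlap in 4165 of the 7453 tested probe sets (55.9%, against 33.3% by chance with 2 against 2 arrays), among them all 591 that were called.

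The counts depended on the variance model of limma and on single arrays. With eBayes run without a trend of variance on signal they were 44 and 34, an ordinary two-sample test called 0 and 0 (1175 with an unadjusted p below 0.05), and without the filter on dim probe sets they were 172 and 157. Leaving out non-transgenic replicate 1 gave 218 higher and 183 lower, non-transgenic replicate 2 gave 232 and 158, transgenic replicate 1 gave 125 and 171, and transgenic replicate 2 gave 183 and 191. The share of higher among the called probe sets was 51.3%, and 66.4% when each array was centred on its median.

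The largest rises on the log2 scale were those of Krt18, a keratin of simple epithelia, at 3.02 ± 0.20 (SE), and Bex1, at 2.78 ± 0.24. Myl1, the alkali light chain of fast skeletal muscle myosin, rose by 2.21 ± 0.08, from 957 ± 46.0 to 4444 ± 110. Procr, the receptor of protein C, rose by 2.02 ± 0.22, and Hspa1b, an inducible heat shock protein, by 1.90 ± 0.15. Plagl1 (2.07), Avpi1 (1.94), Mthfd2 (1.88) and Pus1 (1.88) were the remaining genes among the 12 largest rises besides Nppa, Ccn2 and Postn. Adjusted p values of these 12 in limma with Benjamini-Hochberg adjustment ran from 0.000108 for Myl1 to 0.0150 for Mthfd2. The calls of Plagl1 (adjusted p = 0.0652 without transgenic replicate 1) and Avpi1 (up to 0.0548 without either transgenic array) ended in limma with Benjamini-Hochberg adjustment when an array was left out. Dim second probe sets for Krt18 and Mthfd2, below the filter, had the opposite sign (-0.25 and -0.01).

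Genes of the fetal and hypertrophy list rose together. Of 20 measured members 13 rose, 0 fell and 7 did not pass the test, and the counts adjusted over the list alone were 14 and 0. Without transgenic replicate 1, 8 rose. Fhl1, a LIM protein of stressed myocardium, rose 3.52-fold, Acta2, smooth muscle alpha-actin, 3.59-fold, and Myh7, the slow beta myosin heavy chain, 2.35-fold. Myh7 signal was 3623 ± 198 against 8576 ± 1282. Skeletal alpha-actin, Acta1, rose 1.79-fold. Nppb, the B-type natriuretic peptide, rose from 4201 ± 302 to 5910 ± 610, a call that ended in limma with Benjamini-Hochberg adjustment without non-transgenic replicate 1 or transgenic replicate 1 (adjusted p up to 0.0738). The list had an adjusted p of 1.15e-12 in camera, limma's set test, with Benjamini-Hochberg adjustment over 29 lists (median log2 change 0.79), and an adjusted p = 0.210 with an estimated correlation.

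Among 31 measured SRF targets of the cytoskeleton and smooth muscle, 10 rose, 1 fell and 20 did not pass the test, and the counts adjusted over the list alone were 14 and 3. Besides Fhl1, Acta1 and Acta2, the actin-severing protein Dstn rose 2.26-fold and the LIM protein Csrp2 rose 3.08-fold. Muscle creatine kinase, Ckm, fell by 0.72 ± 0.13, a call that ended without non-transgenic replicate 2 (adjusted p = 0.0564 in limma with Benjamini-Hochberg adjustment). Camera gave this list an adjusted p of 8.18e-05 in limma with Benjamini-Hochberg adjustment (median log2 change 0.16), and an adjusted p = 0.161 with an estimated correlation. Of 24 immediate early genes, 3 rose (Ccn2, Ier3 and Nr4a1), 0 fell and 21 did not pass the test, with 6 and 0 adjusted over the list alone; after median centring 5 rose, and without transgenic replicate 2 the counts were 2 and 1. Their adjusted p was 0.0124 in camera of limma with Benjamini-Hochberg adjustment, 0.0588 with the lowest 60% of probe sets left out, and adjusted p = 0.210 with an estimated correlation. Nr4a1 kept its call in limma with Benjamini-Hochberg adjustment in 1 of the 4 fits that left out an array (adjusted p up to 0.147).

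**Figure D1:**
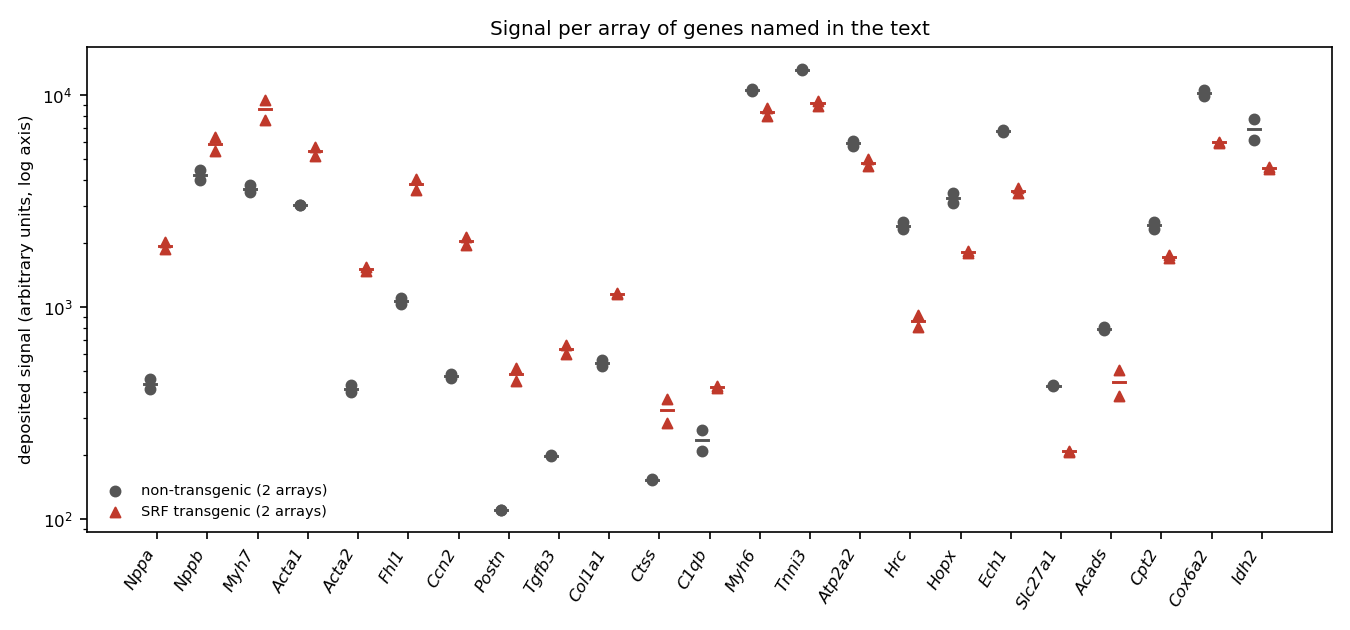
Deposited signal on each array (arbitrary units, log axis) of 23 genes chosen for the figure from those described in the text, for 2 non-transgenic arrays (grey circles) and 2 SRF transgenic arrays (red triangles), with a bar at each group's mean. The transgenic arrays lie above the non-transgenic arrays for Nppa, Myh7, Ccn2 and Postn and below them for Hrc, Hopx, Ech1 and Cox6a2.

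Extracellular matrix genes were higher in transgenic ventricle. Of 34 measured members 15 rose, 0 fell and 19 did not pass the test, with 19 and 1 adjusted over the list alone. Periostin, Postn, secreted by activated fibroblasts, rose 4.11-fold from 111 ± 0.424 to 484 ± 49.7, and the growth factor Tgfb3 rose 3.08-fold from 199.9 ± 2.97 to 634 ± 41.4. The proteoglycan Bgn rose 2.18-fold and the collagen chain Col1a1 2.10-fold, but second probe sets for them (log2 change 0.45 and 0.25) did not pass limma with Benjamini-Hochberg adjustment (adjusted p = 0.0879 and 0.227). Fibroblast markers, of which Col1a1, Col1a2, Col3a1, Dcn and Lum also stand in the matrix list, rose in 11 of 19 cases, with 0 lower and 8 not past the test (14 and 2 adjusted over the list alone); without transgenic replicate 1, 7 rose. Among them were Mgp (2.46-fold), Mfap5 (2.54-fold) and Fbln2 (log2 change 0.81 ± 0.09); a second probe set for Mfap5 gave -0.05. In camera of limma with Benjamini-Hochberg adjustment the adjusted p was 2.02e-09 for the matrix list (median log2 change 0.44) and 1.24e-07 for the fibroblast list (0.53). Each had an adjusted p = 0.161 with an estimated correlation.

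Macrophage and monocyte markers rose in 6 of 11 cases with 0 lower, and 5 did not pass the test (10 and 0 adjusted over the list alone). Without non-transgenic replicate 1 or transgenic replicate 2, 3 rose. The lysosomal protease Ctss rose 2.04-fold and the complement subunit C1qb 1.76-fold, while a dim second probe set for C1qb had a log2 change of 0.10 (adjusted p = 0.858 in limma with Benjamini-Hochberg adjustment). Of 24 measured genes of complement, MHC and the interferon response, 4 rose, 1 fell and 19 did not pass the test (5 and 1 adjusted over the list alone). The class II antigen presentation genes Cd74 (1.96-fold) and H2-Aa (1.93-fold) rose with C1qb and C1qc, while Igtp, an interferon-inducible GTPase, fell by 1.06 ± 0.23. The rise of C1qc ended without non-transgenic replicate 1 or transgenic replicate 2 (adjusted p up to 0.0515 in limma with Benjamini-Hochberg adjustment). The fall of Igtp ended in limma with Benjamini-Hochberg adjustment without non-transgenic replicate 2 or transgenic replicate 2 (adjusted p up to 0.112). Camera of limma with Benjamini-Hochberg adjustment gave adjusted p values of 3.95e-07 for the macrophage list (adjusted p = 0.161 with an estimated correlation) and 0.0102 for the complement and MHC list (adjusted p = 0.625 with an estimated correlation). The latter ended without non-transgenic replicate 1 (adjusted p = 0.176 in camera with Benjamini-Hochberg adjustment).

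Genes of fatty acid oxidation were lower in transgenic ventricle. Of 31 measured members 18 fell, 0 rose and 13 did not pass the test, with 0 higher and 24 lower adjusted over the list alone. The number lower was 12 after median centring, 10 without non-transgenic replicate 2, and 11 without non-transgenic replicate 1 or transgenic replicate 2. Ech1, which isomerises unsaturated fatty acyl-CoA, was 1.91-fold lower, from 6755 ± 126 to 3540 ± 146, and the fatty acid transporter Slc27a1 fell from 427 ± 4.53 to 209 ± 1.98. Eci1 (log2 change -0.61 ± 0.07), Acaa2 (-0.63 ± 0.08) and Crat (-0.62 ± 0.09) fell as well. The short-chain dehydrogenase Acads fell by 0.84 ± 0.14 and the carnitine palmitoyltransferase Cpt2 by 0.49 ± 0.08; without non-transgenic replicate 2 neither passed in limma with Benjamini-Hochberg adjustment (adjusted p = 0.0551 and 0.0511). The list had an adjusted p of 8.08e-12 in camera of limma with Benjamini-Hochberg adjustment (median log2 change -0.49), and an adjusted p = 0.161 with an estimated correlation.

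Subunits of the respiratory chain and ATP synthase fell in 16 of 44 cases, with 0 higher and 28 not past the test (0 higher and 30 lower adjusted over the list alone). The falls were small, and the number called depended on the scaling and on single arrays: 7 fell after median centring, 8 after quantile normalization, 7 without non-transgenic replicate 2 or transgenic replicate 2, and 8 without transgenic replicate 1. Among the largest were the muscle-type cytochrome c oxidase subunits Cox6a2 (1.71-fold lower, 10243 ± 451 against 5985 ± 69.8), Cox8b (1.72-fold) and Cox7a1 (1.44-fold). Of 20 measured genes of the citric acid cycle, 7 fell, 0 rose and 13 did not pass the test (0 higher and 11 lower adjusted over the list alone), among them mitochondrial isocitrate dehydrogenase Idh2, which was 1.52-fold lower. Of the cycle 2 fell after median centring (Idh2 and Dlst), 5 after quantile normalization, 3 without either non-transgenic array, 1 without transgenic replicate 1 and 2 without transgenic replicate 2. In camera of limma with Benjamini-Hochberg adjustment the adjusted p was 2.25e-13 for the respiratory chain (median log2 change -0.29) and 5.47e-06 for the cycle (-0.23). Each had an adjusted p = 0.161 with an estimated correlation.

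Adult sarcomere genes fell in 8 of 21 cases with 0 higher, and 13 did not pass the test (1 higher and 11 lower adjusted over the list alone). The number lower was 4 after median centring or quantile normalization, 3 without non-transgenic replicate 2, and 5 without non-transgenic replicate 1 or transgenic replicate 2. The ventricular essential light chain Myl3 was 1.49-fold lower and cardiac troponin I, Tnni3, 1.44-fold lower. After quantile normalization their log2 changes were nearer 0, at -0.29 and -0.27 against -0.57 and -0.53. The alpha myosin heavy chain Myh6 was 1.27-fold lower, and Myl2, the ventricular regulatory light chain, 1.22-fold lower. Both of these calls ended under quantile normalization in limma with Benjamini-Hochberg adjustment (log2 change -0.13, adjusted p = 0.269, for Myh6), under median centring (adjusted p = 0.0628 and 0.0634), and in 3 of the 4 fits that left out an array (adjusted p up to 0.0812 and 0.160). Among the brightest probe sets, Myl2 held the same ranks in both groups, so that its change was then 0.00. The list had an adjusted p of 7.95e-05 in camera of limma with Benjamini-Hochberg adjustment, 0.161 after quantile normalization, and an adjusted p = 0.161 with an estimated correlation.

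Calcium handling genes moved both ways. Of 15 measured members Casq1, the skeletal calsequestrin, rose 2.80-fold, while Hrc, the calcium sensor S100a1 (3772 ± 212 against 2696 ± 108) and the calcium pump Atp2a2 (1.23-fold) fell and 11 did not pass the test (1 and 3 adjusted over the list alone). The call of Atp2a2 ended under quantile normalization and median centring in limma with Benjamini-Hochberg adjustment (adjusted p = 0.122 and 0.126), and without any 1 of the 4 arrays. The list did not pass camera in limma with Benjamini-Hochberg adjustment (adjusted p = 0.350). Ion channel and gap junction genes had 2 lower, 0 higher and 15 not past the test of 17 measured (0 higher and 5 lower adjusted over the list alone). Those were the potassium channel Kcnk3 (441 ± 107 against 213 ± 20.7; adjusted p = 0.0515 in limma with Benjamini-Hochberg adjustment without non-transgenic replicate 2) and the sodium pump regulator Fxyd1, which lost its call without 3 of the 4 arrays (adjusted p up to 0.109) and after quantile normalization (0.0697). Their list had an adjusted p of 0.00322 in camera of limma with Benjamini-Hochberg adjustment (median log2 change -0.22), and an adjusted p = 0.210 with an estimated correlation. The cardiac homeodomain protein Hopx, which binds SRF, was 1.79-fold lower (3277 ± 228 against 1825 ± 31.3) and was the 1 called member of 18 measured transcription factors (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.889 in limma with Benjamini-Hochberg adjustment).

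Heat shock genes rose in 3 of 27 cases and fell in 1, with 23 not past the test (7 and 3 adjusted over the list alone; 6 and 0 past the test after median centring). Hspa1b (3.73-fold), Hspa1a (3.37-fold) and Hsp90aa1 (2.37-fold) rose, and the mitochondrial chaperone Hspa9 fell by 0.51 ± 0.11, a call that ended in limma with Benjamini-Hochberg adjustment without non-transgenic replicate 1 or transgenic replicate 2 (adjusted p up to 0.122). Hspa1a and Hspa1b are near-identical genes whose probe sets can share signal. Proteasome and ubiquitin genes had Psmd4 and Psma6 higher, 0 lower and 26 not past the test of 28 measured (2 and 0 adjusted over the list alone). Psmd4 rose 1.54-fold, and both calls ended when single arrays were left out in limma with Benjamini-Hochberg adjustment (adjusted p up to 0.105 for Psmd4 and 0.0947 for Psma6). In camera of limma with Benjamini-Hochberg adjustment the adjusted p was 0.00917 for heat shock and 0.0102 for the proteasome, and each had an adjusted p = 0.210 with an estimated correlation.

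Glycolysis and antioxidant genes had members in both directions. Of 24 measured glycolysis genes 5 rose, 3 fell and 16 did not pass the test (6 and 6 adjusted over the list alone; 6 and 1 past the test after median centring). Without non-transgenic replicate 1 the counts were 4 and 0, and without transgenic replicate 1 or 2 they were 3 and 1 or 3 and 0. Hexokinase Hk1 rose 1.95-fold and the glucose transporter Slc2a1 2.23-fold, while muscle glycogen phosphorylase Pygm was 1.31-fold lower. Of 29 antioxidant genes 4 rose, 3 fell and 22 did not pass the test (5 and 6 adjusted over the list alone; 4 and 1 past the test after median centring, 3 and 1 or 2 and 1 without non-transgenic replicate 1 or 2, 2 and 0 or 2 and 2 without transgenic replicate 1 or 2), with extracellular glutathione peroxidase Gpx3 up 1.77-fold, thioredoxin reductase Txnrd1 up 2.07-fold and mitochondrial peroxiredoxin Prdx3 1.41-fold lower. Calls of Slc2a1, Pygm and Prdx3 ended in limma with Benjamini-Hochberg adjustment when single arrays were left out (adjusted p up to 0.122, 0.0671 and 0.0503). Neither list passed camera in limma with Benjamini-Hochberg adjustment (adjusted p = 0.954 for each), and each had a negative median with a positive mean and test direction.

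Markers of other cell types were examined beside these groups. Of 15 measured endothelial markers Eng rose 1.39-fold, Aqp1 and Tie1 were 1.57-fold and 1.53-fold lower, and 12 did not pass the test (1 and 2 adjusted over the list alone; camera adjusted p = 0.296 in limma with Benjamini-Hochberg adjustment). The calls of Eng and Tie1 each held in 1 of the 4 fits that left out an array (adjusted p up to 0.0698 and 0.112 in limma with Benjamini-Hochberg adjustment). In the smooth muscle list Acta2 was the 1 called gene of 9 (1 and 0 adjusted over the list alone; adjusted p = 0.497 in camera of limma with Benjamini-Hochberg adjustment). Adipocyte markers had Adipoq (2.56-fold) and Car3 (2.09-fold) lower and 6 of 8 not past the test (0 higher and 3 lower adjusted over the list alone); Car3 did not pass without non-transgenic replicate 2 (adjusted p = 0.0637 in limma with Benjamini-Hochberg adjustment). That list had an adjusted p of 0.00343 in camera of limma with Benjamini-Hochberg adjustment, 0.122 without non-transgenic replicate 2, and an adjusted p = 0.519 with an estimated correlation. Lymphocyte markers had Ighm lower among 7 measured (1.94-fold; 0 higher and 2 lower adjusted over the list alone), with an adjusted p of 0.0822 in camera of limma with Benjamini-Hochberg adjustment, 0.0379 without non-transgenic replicate 1 and 0.0408 after median centring. Atrial markers had Nppa and Myl7 higher and Stard10 lower of 9 (4 and 3 adjusted over the list alone; 4 higher without non-transgenic replicate 2; adjusted p = 0.344 in camera of limma with Benjamini-Hochberg adjustment).

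Skeletal muscle markers had Myl1, Casq1 and Acta1 higher and Atp2a1 and Ckm lower of 11 (4 and 4 adjusted over the list alone; 0 lower without non-transgenic replicate 2; adjusted p = 0.552 in camera of limma with Benjamini-Hochberg adjustment). Krt18 and Uchl1 were the called members of 9 neuronal, Schwann and epicardial markers (2 and 1 adjusted over the list alone; adjusted p = 0.665 in camera of limma with Benjamini-Hochberg adjustment). Cell cycle genes had Ccnd2, a G1 cyclin, 2.27-fold higher among 23 (1 and 0 adjusted over the list alone; 2 higher without non-transgenic replicate 2; camera adjusted p = 0.552 in limma with Benjamini-Hochberg adjustment). Clock genes had Bhlhe40 higher among 12, a call that held in 1 of the 4 fits that left out an array (adjusted p up to 0.157 in limma with Benjamini-Hochberg adjustment; 1 and 0 adjusted over the list alone; camera adjusted p = 0.954 in limma with Benjamini-Hochberg adjustment). No member of 17 apoptosis genes (camera adjusted p = 0.980) or 15 ribosomal protein genes (0.986) passed limma with Benjamini-Hochberg adjustment, over all probe sets or adjusted over the list alone, but 1 apoptosis gene fell without transgenic replicate 1 and 1 rose with a replicate block. The alpha globin Hba-a1 had a log2 change of -0.21 ± 0.06 and did not pass, with 12791 ± 694 against 11063 ± 417. With Alas2 and Slc4a1 it made 3 measured erythroid genes, too few for a set test (0 higher and 1 lower adjusted over the list alone).

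**Figure D2:**
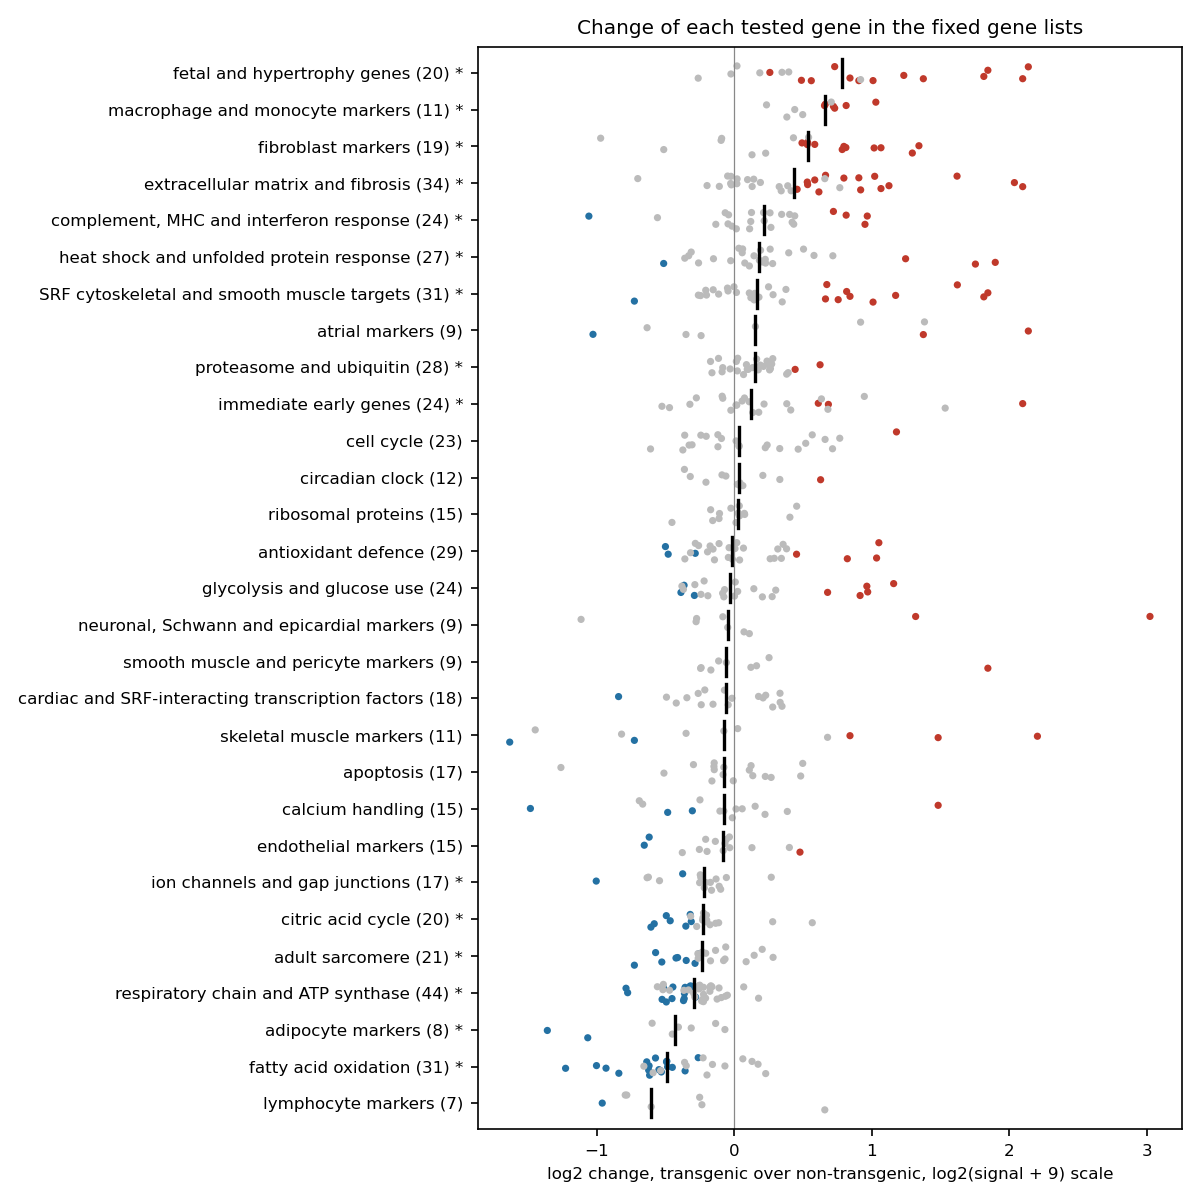
Log2 change of each tested gene (points) in the 29 gene lists tested, with list medians as black bars, numbers of tested genes in parentheses, and an asterisk where the list passed camera at the preset correlation. Red and blue points are genes higher or lower in transgenic ventricle by limma with Benjamini-Hochberg adjustment; the fetal and hypertrophy list has the highest median (0.79), and of the lists that passed, fatty acid oxidation has the lowest (-0.49).

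In all, 15 of the 29 lists passed camera, 9 higher and 6 lower in transgenic ventricle. With an estimated correlation 0 passed, and the smallest adjusted p was 0.161 (camera of limma with Benjamini-Hochberg adjustment). The estimate lay above the preset 0.01 for some lists, such as fetal and hypertrophy genes (0.23). For fatty acid oxidation it lay below (-0.02), yet the unadjusted camera p went from 8.36e-13 to 0.0146. Correlation between genes therefore does not account for that loss, and the few residual degrees of freedom limit this version. Fry, which asks whether the genes of a list move one way on balance, called 12 lists, of which 11 were among those called by camera. Its mixed test, for change in either direction, called 28. The median of each of the 15 lists kept its sign under all alternatives run. Of the genes named above, Fhl1, S100a1, Col1a2, Ighm and Aqp1 also had other probe sets of opposite sign, which were below the filter or did not pass the test. Further tested probe sets of Ckm, Col3a1, Acads, Crat and Tie1 had the same sign and did not pass.

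The largest falls were in transcripts of hepatocytes. The major urinary protein Mup3, measured by a probe set that can also bind its relatives, fell from 586 ± 316 to 6.55 ± 2.47, apolipoprotein Apoa1 from 671 ± 234 to 10.85 ± 0.919, and serum albumin, Alb, from 1296 ± 624 to 43.0 ± 10.3. Transgenic signals of Mup3 and Apoa1 were near the pseudocount of 9, and their log2 changes of -5.16 and -5.05 moved most with it, to -6.42 and -5.91 with none and to -4.52 and -4.53 with a doubled one. That of Alb, -4.58, moved most with the non-transgenic arrays, to -5.08 without replicate 1 and -4.07 without replicate 2. Mup5, Kng1, Serpina1e, Cyp3a11, Fabp1, Serpina1c, Serpina1b, Ces3a and Fga completed the 12 largest falls. Of 58 tested genes in a hepatocyte list written after these values were seen, 31 fell and 0 rose. On the single arrays Alb read 855.5 and 1738 in non-transgenic ventricle and 50.3 and 35.7 in transgenic ventricle.

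Outside the hepatocyte list, 247 probe sets were lower, 41 of them at least 2-fold; the genes in this paragraph were chosen by the rule for named genes applied again after the values were seen. The ephrin Efnb3 was 3.19-fold lower, from 1000 ± 32.7 to 307 ± 4.03. The uncharacterised gene 0610005C13Rik fell by 2.43 ± 0.26 on the log2 scale, Cpxm2 by 1.72 ± 0.32, and the fast skeletal calcium pump Atp2a1 by 1.63 ± 0.27. Without non-transgenic replicate 2, Cpxm2 (adjusted p = 0.0606) and Atp2a1 (adjusted p = 0.0552) did not pass limma with Benjamini-Hochberg adjustment. Tm7sf2, Gnb3, Hrc, Entpd5, Egf, Adipoq, Hmces and an immunoglobulin kappa probe set completed this group. A second probe set for Tm7sf2 had the same sign and did not pass. Liver RNA was not tested as a source of the falls in this paragraph. Egf and Hmces each held in 1 of the 4 fits that left out an array (adjusted p up to 0.106 and 0.134 in limma with Benjamini-Hochberg adjustment).

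Sex-linked genes were read on each array as a check. Xist signal was 101 and 86.4 in non-transgenic and 124 and 148 in transgenic ventricle, and Eif2s3y signal was 55.2 and 51.7 against 27.6 and 24.4; neither passed limma with Benjamini-Hochberg adjustment (adjusted p = 0.138 and 0.0840). With 2 measured genes the list had no set test (1 higher and 1 lower adjusted over the list alone). The dim Y-linked genes Uty (32.1 and 33.2 against 8.30 and 11) and Kdm5d (10.4 and 12.2 against 2.10 and 3.70) were below the filter. The sex of the animals is not given in the sources used here. Each of these genes split by group without overlap, the Y-linked ones higher on both non-transgenic arrays and Xist on both transgenic arrays. A difference in the mix of sexes between the groups therefore cannot be told apart from the transgene. The ratio of 3′ to 5′ signal was 1.11 to 1.30 for actin and 0.879 to 0.954 for Gapdh on the 4 arrays.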

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

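The tests in this part were chosen after the results were seen, apart from the brightness-matched random lists, which were set down before their outcome was known. A control probe set for the 5′ end of 18S ribosomal RNA, outside the main measurement, had a mean signal of 19.95 on the transgenic arrays (23.7 and 16.2). On the non-transgenic arrays it was 2.60. This dim signal split by group, as the hepatocyte transcripts did, and the cause was not tested. Any difference in sample preparation between the groups cannot be told apart from the transgene.

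Hepatocyte transcripts, led by Mup3, Apoa1 and Alb, were higher on both non-transgenic arrays. Quantile normalization left the median log2 change of the 58 tested hepatocyte genes, called or not, at -1.15, against -1.20 as deposited. That argues against scaling of the arrays. For the 31 called genes it was -2.44 against -2.50, but they were chosen for their falls, so this adds no support. RNA from liver in the non-transgenic samples is a candidate explanation: 72.4% of 127 hepatocyte genes were lower on both transgenic arrays (29.0% of all probe sets outside the controls were, and 16.7% would be by chance), but the pancreas list reached 42.9%, so the criterion of at least 2 times the other organs was missed. A further comparison, added once that criterion had been missed and the counts were known, set the 31 of 58 tested hepatocyte genes called lower against 1 of 16 genes of other organs (two-sided Fisher exact p = 0.000558), and so adds no independent evidence. Expression by the heart itself cannot be told apart from it, since the excess follows the groups; the level in non-transgenic replicate 2 was 1.81 times that in replicate 1 (median log2 ratio 0.85, higher for 30 of 31 genes, against -0.02 over the other probe sets).

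Genes of fatty acid oxidation and of the respiratory chain were lower in transgenic ventricle. Liver RNA in the non-transgenic samples was argued against as the whole of the fall: it would raise non-transgenic replicate 2 over replicate 1, but over all tested members, called or not, the log2 ratio, less that of probe sets of like brightness, lay below that predicted from the lower quartile of the hepatocyte excess ratio (1.62), with a median difference of -0.172 (95% bootstrap interval over genes -0.29 to -0.07) for 31 fatty acid oxidation genes and -0.0801 (-0.12 to -0.05) for 44 of the respiratory chain (upper limits -0.06 and -0.04 without the brightness term), against 0.33 (0.10 to 0.42) for 58 hepatocyte genes. The hepatocyte value was favoured in advance, because the prediction used the lower quartile over called hepatocyte genes, so it adds no support. The intervals resample genes within the pair of non-transgenic arrays and hold no spread between arrays. They cannot show whether another pair would give the same. The predicted log2 ratios were themselves small, at 0.20 for fatty acid oxidation and 0.12 for the respiratory chain. A shift of bright probe sets was argued against as the whole of the change. The list medians lay at percentile 0 and 0.270 of 10000 random lists of like brightness. However, lists matched to the respiratory chain had themselves a median of -0.16. A lower share of cardiomyocyte RNA was tested against the adult sarcomere list: fatty acid oxidation lay below it (median difference -0.26, permutation p = 0.0327 over genes, adjusted p = 0.0392 over 6 tests with Benjamini-Hochberg adjustment; genes are not independent replicates). The respiratory chain did not pass (median difference -0.06, permutation p = 0.208, adjusted p = 0.208 with Benjamini-Hochberg adjustment). The sarcomere list shares Actc1, Tpm1, Des and Ckm with the SRF target list, so the transgene may change it within each cardiomyocyte. It is therefore no neutral gauge, and a lower cardiomyocyte share stays open for both lists. An effect of the transgene stays open too, and a difference in the sex of the animals cannot be told apart from it here. As a hypothesis, the fall of fatty acid oxidation genes may be biological.

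Fibroblast and macrophage markers were higher in transgenic ventricle. A lower share of cardiomyocyte RNA would raise markers of other cell types alike, but fibroblast markers lay 0.61 above endothelial markers (permutation p = 0.00512, adjusted p = 0.00768) and macrophage markers 0.74 above them (permutation p = 0.00011, adjusted p = 0.00066, with Benjamini-Hochberg adjustment over 6 tests). Genes are not independent replicates, so these p values do not measure the spread between samples. Endothelial markers are no neutral gauge either, since Eng was called higher and Aqp1 and Tie1 lower among them. A lower cardiomyocyte share therefore stays open here too. The fibroblast median lay at percentile 100 of 10000 random lists of like brightness, which argues against a shift of probe sets of that brightness. More fibroblasts and macrophages, or more of these transcripts per cell, are both open, and no value here separates them. As a hypothesis, the rise may be biological. The sex-linked genes split by group, so a difference in the mix of sexes cannot be told apart from the transgene.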

How the results depend on the processing

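The alternative without the hepatocyte list was chosen after seeing the data, and the others were planned. The counts of 303 higher and 288 lower probe sets became 172 and 157 with no filter on dim probe sets, 44 and 34 with eBayes without a trend, 0 and 0 with an ordinary two-sample test (smallest adjusted p 0.0951 with Benjamini-Hochberg adjustment in place of limma's moderated test, 1175 with an unadjusted p below 0.05), and 477 and 484 at an adjusted p below 0.1. The cause was not tested, apart from the larger number tested (12422) without a filter and the looser threshold itself. Leaving out 1 array, where the lone array is assumed to vary like the other group, gave 125 to 232 higher and 158 to 191 lower. Replicate numbers were shared between groups, but the deviations of same-numbered arrays correlated at -0.06, and a replicate block gave 348 higher and 345 lower, with 571 of the 591 calls shared. Under the other alternatives the counts stayed within 1.5 times, and 0 of the calls tested in each changed direction (506 to 591 of the 591). Median centring, which moved the median change of all probe sets from -0.01 to 0.07, gave 390 and 197, and quantile normalization 304 and 269. With eBayes without a trend 127 of the named genes past the threshold lost their call, and with no filter on dim probe sets 67 did. The counts of called genes given for the lists depend on these settings too. Of 164 named genes past the threshold, 134 stayed past it under both median centring and quantile normalization, 83 without each array in turn, and 35 under all settings except the ordinary test. Gene lists past the threshold numbered 14 to 16 under the alternatives run for lists, which left out the ordinary test and the looser threshold, and 0 with an estimated correlation; the block changed no list's call. Mean log2 changes near 0 changed sign for apoptosis (0.0212 with median centring, 0.0520 with the lowest 60% left out), ribosomal proteins (-0.0928 with no filter, -0.0119 to 0.0328 without 1 array), transcription factors (0.0131 with median centring), skeletal muscle (-0.0151 with a pseudocount of 4.5, -0.0593 with none, -0.172 with no filter, -0.0532 to 0.0886 without 1 array) and the circadian clock (-0.0378 to 0.0903 without 1 array); the cause was not tested. The same held for Alas2 (-0.414 to 0.169) and Slc4a1 (-0.226 to 0.296), neither of them called. Srf is not analysed here, so the overexpression was not checked. Dim probe sets limit what can be seen, because the pseudocount of 9 compresses their change.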

Other observations

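The gene groups and tests in this part were chosen after the values were seen, so the camera and permutation p values describe the groups and add no independent evidence. Genes of the TGF-beta family, with their inhibitors and SMADs, were higher in transgenic ventricle: 6 of 19 tested rose and 0 fell, and camera of limma gave an adjusted p of 2.22e-06 with Benjamini-Hochberg adjustment over 12 such groups (median log2 change 0.51, or 0.24 over all 28 genes with those below the filter; adjusted p = 0.179 with an estimated correlation). Beside Tgfb3, the inhibitory Smad7 (0.82) and Smad6 (0.76), the transcriptional regulator Id2 (1.16), Fstl1 (0.83) and the latent TGF-beta binding protein Ltbp4 (0.45) rose. Of these 6 calls, those of Tgfb3 and Id2 held without each array in turn; Smad7 held in 2 of the 4 fits, and Smad6, Fstl1 and Ltbp4 in 1 (adjusted p up to 0.0733, 0.0652, 0.0599 and 0.144 in limma with Benjamini-Hochberg adjustment). Tubulins of non-muscle cells had Tubb2a (0.75) and Tuba1c (0.38) higher and 0 lower of 7 (adjusted p = 0.00102 in camera of limma with Benjamini-Hochberg adjustment; adjusted p = 0.210 with an estimated correlation); the call of Tuba1c ended without any 1 of the 4 arrays (adjusted p up to 0.108 in limma with Benjamini-Hochberg adjustment). Both groups kept a positive median after median centring (0.59 and 0.36) and quantile normalization (0.52 and 0.27).

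Peroxisomal genes fell in 7 of 22 cases, with 0 higher. They included Pex11a (-0.75), which takes part in peroxisome division, Hsdl2 (-0.72) and Pxmp2 (-0.66), along with Ech1, Crat and Eci2, which the fatty acid oxidation list also holds. Pex11a held in 1 of the 4 fits that left out an array (adjusted p up to 0.0786) and Eci2 in 3 (0.0503 without non-transgenic replicate 1, in limma with Benjamini-Hochberg adjustment). Camera of limma gave an adjusted p of 2.22e-06 with Benjamini-Hochberg adjustment (median log2 change -0.30; adjusted p = 0.179 with an estimated correlation), and the median was -0.22 after median centring and -0.32 after quantile normalization. Hepatocyte transcripts fell on the same arrays (median -1.20 over 58 tested genes), and liver is rich in peroxisomes. The log2 ratio of non-transgenic replicate 2 over 1 had a median of 0.04 over all 25 peroxisomal genes and 0.51 over all 127 hepatocyte genes, those below the filter included. Over the 22 and 58 tested genes, and without the pseudocount, it was 0.02 and 0.73. Against the ratio predicted for liver RNA the tested peroxisomal genes lay at -0.20 (95% bootstrap interval -0.31 to -0.01) with a correction for brightness and at -0.19 (-0.31 to 0.02) without it, so liver RNA stays open for this group. Desmosomal genes had Dsc2 (-1.06) and Dsg2 (-0.93) lower among 7, and as a group did not pass camera in limma with Benjamini-Hochberg adjustment (adjusted p = 0.149); Dsc2 held in 0 and Dsg2 in 1 of the 4 fits that left out an array (adjusted p up to 0.109 and 0.143).

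Thiol defence genes were grouped by compartment and glycolysis genes by isoform once their directions had been seen, so the permutation and camera p values of these groups restate what prompted the grouping. Of 14 cytosolic thiol defence genes 3 rose (Txnrd1, Gclm and Txn1) and 1 fell (Prdx2), and of 8 mitochondrial ones 5 fell (Gstk1, Nnt, Mgst3, Prdx3 and Txn2) and 0 rose. Gstk1 is also counted among peroxisomal genes. The calls of Txnrd1, Gstk1, Nnt and Mgst3 held without each array in turn, Prdx3 ended without transgenic replicate 1 (adjusted p = 0.0503), Gclm and Txn2 held in 1 of the 4 fits (up to 0.0846 and 0.165), and Txn1 and Prdx2 in 0 (up to 0.143 and 0.158, all in limma with Benjamini-Hochberg adjustment). Prdx2 also ended under median centring (adjusted p = 0.115) and quantile normalization (0.119), and Txn2 under median centring (0.0623), in limma with Benjamini-Hochberg adjustment. The cytosolic median lay 0.50 above the mitochondrial one (exact permutation p = 0.00298 over 319770 groupings, adjusted p = 0.00596 over 6 tests with Benjamini-Hochberg adjustment). In camera of limma with Benjamini-Hochberg adjustment the mitochondrial group passed (adjusted p of 3.06e-05, median log2 change -0.50; adjusted p = 0.179 with an estimated correlation) and the cytosolic group did not (adjusted p of 0.474, median -0.00; adjusted p = 0.718 with an estimated correlation).

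Of 11 genes grouped as non-muscle isoforms of glycolysis and glycogen use 5 rose and 0 fell, and of 13 grouped as muscle isoforms 5 fell and 0 rose. The muscle group also holds Ldhb, the heart subunit of lactate dehydrogenase, and Pdk4, a pyruvate dehydrogenase kinase. Second probe sets of Aldoa (-0.06) and Pfkp (0.62) kept the sign and did not pass limma with Benjamini-Hochberg adjustment (adjusted p = 0.702 and 0.113). Of the rises, Hk1 and Pgam1 held without each array in turn, Eno2 (1.49) ended without transgenic replicate 1 (adjusted p = 0.0969 in limma with Benjamini-Hochberg adjustment), and Slc2a1 and Pfkp held in 1 of the 4 fits (up to 0.122 and 0.0928). None of the falls held in all 4: Pdk4 held in 2 (adjusted p up to 0.107), Fbp2 (-0.83) and Pygm in 1 (0.160 and 0.0671), and Aldoa and Ldhb in 0 (0.108 and 0.157, in limma with Benjamini-Hochberg adjustment). Median centring ended Aldoa, Ldhb and Pdk4 (adjusted p = 0.0709, 0.0769 and 0.0554), and quantile normalization ended Aldoa (0.369, in limma with Benjamini-Hochberg adjustment). The group medians were 0.30 and -0.29 (difference 0.59, permutation p = 0.00028, adjusted p = 0.00084 with Benjamini-Hochberg adjustment). Camera of limma with Benjamini-Hochberg adjustment gave an adjusted p of 0.000621 for the non-muscle and 0.00127 for the muscle group, each with an adjusted p = 0.198 with an estimated correlation.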
